A study of Strongylocentrotus purpuratus with 10 samples.

How the data were processed

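Whole embryos were sampled at 24 h after fertilisation. The labels describe 10 samples in 4 groups: 3 control and 3 brachyury morphant RNA libraries with 100 bp paired reads, and 2 antibody and 2 input ChIP libraries with 50 bp single reads. Zygotes received 2 to 4 pl of the morpholino CGCTCATTGCAGGCATAGTGGCG at 200 µM. The labels do not say whether control embryos were injected.

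The submitters' processing notes list Trimmomatic 0.38, Salmon 0.11.3, DESeq2 1.28.1 and BWA 0.7.17, with no role or order. The peak caller is not given in the sources used here. The log2 fold changes are those the authors deposited for morphants and controls, and the numerator is not given per the file headers. The p-value and adjusted p-value of each gene are the authors' own, and the deposited table holds only genes with an adjusted p under 0.05, the largest being 0.04995. Peak score, antibody signal, input signal and fold enrichment are the values the authors deposited for each peak, per the file headers. The distribution score is a fraction between 0 and 1, per the file headers, and the authors' false discovery rate is deposited in percent. The authors' scaling of signal is not given in the sources used here. Each antibody library has its own list with its own input, per the labels, and the rule by which the authors combined the lists is not given in the sources used here.

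Gene IDs of the table matched the Spur_5.0 gene table for all 3542 genes. Peak coordinates are on Spur_5.0 scaffolds and are given from 1. The gene table names no scaffold for nuclear genes. Its rows run in blocks of rising start, and the 21 blocks longer than 20 Mb were paired in order with the 21 scaffolds that hold over 100 peaks of library 2. In all 21 pairs every peak ends before the last gene end, which 0 of 100000 random pairings achieved. Genes on other scaffolds were left out of the peak comparisons. A peak was given to the gene span nearest to its midpoint within 10 kb.

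No gene was tested again, because values per library were not used here. The design fixed before the data were examined called for counts of called genes when only the authors' statistics are at hand, and these were used. Lists were compared by the share of positive genes with a two-sided exact binomial test against the share among all 3542 genes, with Benjamini-Hochberg adjustment over 18 lists. The table holds only genes past the threshold, so enrichment of a list and a count adjusted over the list alone were not possible. Names were matched without letter case, prefix, punctuation and the copy mark at the end of a name. The handling of the copy mark and the removal of 2 rows whose description contradicts the name were decided after seeing the data. The removal was not complete. Clect_2, described as a mucin, was kept, as was Nk7, which the fixed list holds within its tetraspanin entry, and an alternative leaves both out. That alternative still holds SM37 and an Sm30 gene (LOC592088), whose descriptions also differ from their names. Clect genes with different end numbers and different descriptions were counted under the same list member. Peak overlap and position used 1000 random placements within scaffolds, scores 100000 permutations, and binding Fisher's exact test. Genes named are brachyury, the 10 largest changes per direction with a usable name, up to 6 called members per list by adjusted p, genes at the 10 highest combined peaks and bound list members; examples are drawn from these, and the rule's condition on mean level could not be applied. Some list members beyond the first 6 are named as bound genes.

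Alternatives were an adjusted p under 0.01, an absolute log2 fold change of at least 1, the higher-scoring peaks, a fold of at least 5, midpoints within 50 bp, 5 kb and 50 kb distances and each library's list. The brachyury motif and the morpholino target site need genome sequence and are not analysed here. On simulated data, the list test recovered 91.0% of changed lists and called 0.353% of unchanged ones, over 3542 genes. The simulated lists held independent genes, and the changed list was planted as almost wholly negative. The fixed lists hold gene copies and genes that may change together, so these rates need not hold for them. The test of bound genes called 3.8% of simulations without an effect, over 2978 genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.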

Results

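Embryos of the purple sea urchin Strongylocentrotus purpuratus were examined at the blastula stage, 24 h after fertilisation. Brachyury is a T-box transcription factor of the vegetal plate and the oral field. RNA-seq compared 3 libraries of embryos injected as zygotes with a translation-blocking brachyury morpholino and 3 libraries labelled as wild type controls, which the labels call biological replicates. ChIP-seq comprised 2 antibody libraries, each with its own input library. The labels do not say whether the antibody libraries are different antibodies or different samples, and they are called antibody libraries 1 and 2 here. The study asked where Brachyury binds and how its loss changes expression. The differential table and the peak lists give no read totals, so the depth of each library is unknown.

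The differential expression results cover a broad set of developmental genes, with aboral ectoderm and housekeeping genes on the negative side, most skeletogenic genes there too, and the brachyury transcript itself on the positive side. The table does not state which group is the numerator of its fold changes. If it is morphant over control, a negative value means a lower level in morphants, but this could not be read from the file, and the directions are therefore given as positive and negative. The authors' deposited table holds 3542 genes, all with an adjusted p under 0.05, of which 1714 were positive and 1828 negative. The median log2 fold change was 0.93 among positive genes and -1.19 among negative genes of the authors' deposited table. The table holds no gene that failed the threshold, so a gene outside it is either unchanged, unmeasured or below the threshold. It gives no error and no value per library, and its values therefore stand without a spread.

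The brachyury transcript (LOC576774) had a log2 fold change of 1.18 with an adjusted p of 8.71e-05 in the authors' deposited table. A translation-blocking morpholino does not remove the mRNA it binds, so this value is no check of the knockdown.

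Aboral ectoderm genes had the lowest adjusted p of the lists. All 21 genes of this list in the table, from 11 list members, were negative (two-sided exact binomial test against the 48.4% of table genes that were positive, adjusted p = 2.1e-05 over 18 lists). The cytoskeletal actin gene cyiiib had a log2 fold change of -4.36 in the authors' deposited table, and the homeobox genes hox1 (named Hox7 there), HMX and Msx had -2.16, -1.89 and -1.69. An arylsulfatase gene (LOC579315) and the calcium-binding protein gene SPEC1 stood at -1.29 and -1.35 in the authors' deposited table. With 1 gene per list member the 11 members were still all negative, with an adjusted p of 0.0093.

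Skeletogenic genes, which act in the primary mesenchyme that builds the larval skeleton, were negative for 26 of 31 genes (adjusted p = 0.0014). Spicule matrix gene SM30A had a log2 fold change of -3.25 in the authors' deposited table, the homeobox gene Nk7 (LOC580883; the fixed list holds this name within its tetraspanin entry, an unrelated gene) -3.33, the cell surface glycoprotein gene Msp130r3 (LOC579383) -2.80, and the biomineralization gene P16 -1.60. The 5 positive genes, named after their values were seen, were Alx1 (0.90), FoxN2/3 (0.78), Msp130r1 (0.90), MMP14 (1.47) and a gene named Clect_2 but described as a mucin (1.68) in the authors' deposited table. Several of these names stand on more than 1 near-identical gene copy, whose values are uncertain because reads may be divided between copies. Without Nk7 and Clect_2, 25 of 29 genes were negative (adjusted p = 0.00076). These still include SM37, described as a transmembrane protein, and an Sm30 gene (LOC592088), described as collagen-like, both negative in the authors' deposited table. Counting each list member once left 4 positive and 12 negative members and ended the call, with an adjusted p of 0.48.

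Genes of the housekeeping list, all but 1 of them ribosomal protein genes, were negative for all 15 genes from 12 members (adjusted p = 0.00061, and 0.0093 with 1 gene per member). The list was fixed as genes expected to be steady, but 12 of its 20 members are in the table, so it gave no steady reference. Whether a broad difference between the groups also shifted the other lists was not tested. Ribosomal protein genes Rpl8 (LOC592315), Rps3 and Rpl4 had log2 fold changes of -1.70, -1.44 and -1.26 in the authors' deposited table.

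**Figure D1:**
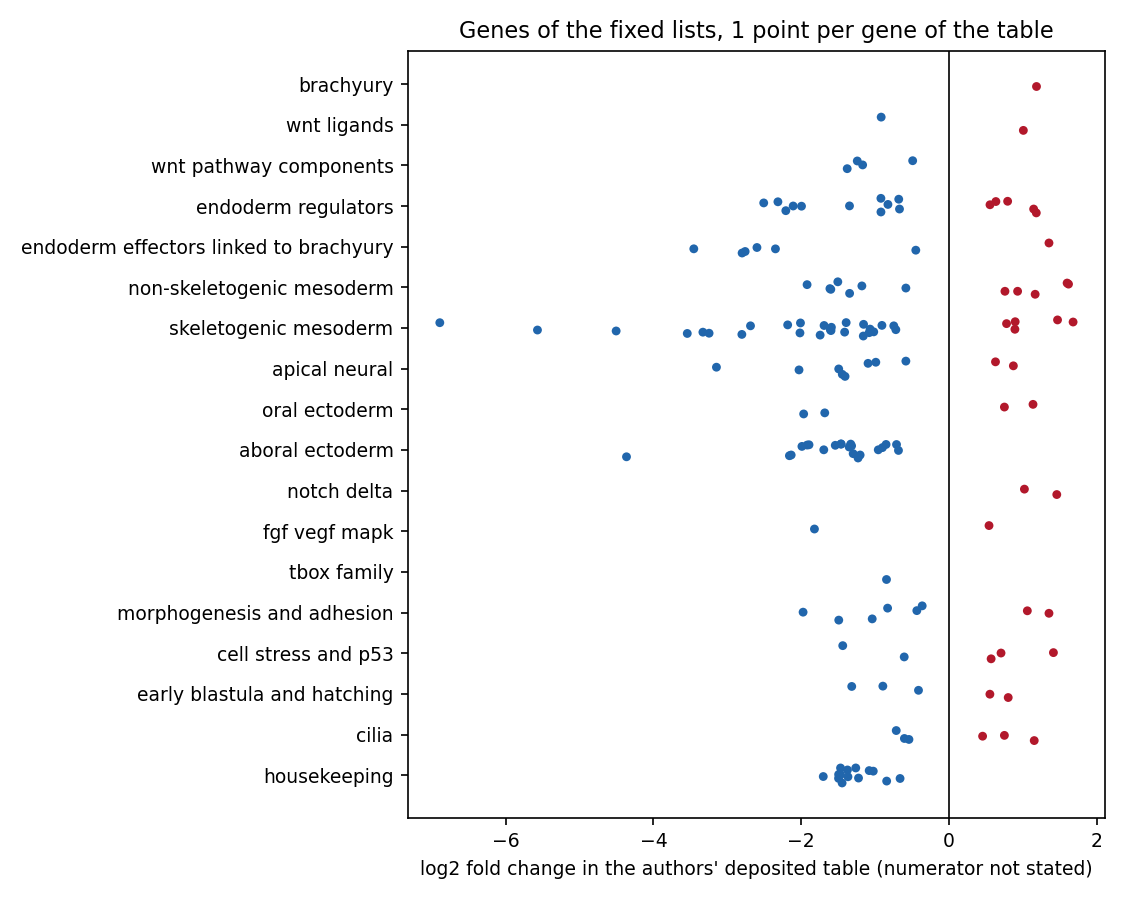
Log2 fold change (x axis) of each gene of the fixed lists present in the authors' deposited table, 1 point per gene, red for positive and blue for negative values; the numerator is not stated. All 21 aboral ectoderm genes and all 15 housekeeping genes lie below 0.

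No other list passed the adjusted threshold, and 10 lists, those with 6 genes or fewer in the table, could not have passed whatever the signs of their genes, with the other lists as they are. The list fixed as endoderm regulators had 5 positive and 11 negative genes (adjusted p = 0.53). Whether each of its genes, among them Nk1, Unc4.1 and SoxB1, acts in the endoderm was not tested, so the split is that of the list. For genes of this list, the authors' deposited table gives Nk1 -2.11, hedgehog (hh) -2.31, FoxA -0.67, SoxB1 -0.82, Unc4.1 (LOC577625) -2.21 and Dac (LOC586986) 0.80 as log2 fold changes. The list of endoderm effectors tied to brachyury in earlier work, assembled from memory, had 1 positive and 6 negative genes (adjusted p = 0.38). Its members Apobec1 (LOC575684) and Orct (LOC585536) stood at -2.60 and -2.80 in the authors' deposited table, and Gelsolin (LOC579255) at 1.36. Another gelsolin-like gene (LOC588119), outside the lists and named after its value was seen, was bound and had -0.87 in the authors' deposited table. Genes of the apical neural territory were positive for 2 and negative for 8 (adjusted p = 0.38), with Isl at -3.15, Ac/Sc at -2.03 and NK2.1 at -1.44 in the authors' deposited table.

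Non-skeletogenic mesoderm genes went both ways, with 5 positive and 7 negative genes (adjusted p = 1). The regulators GataC and Ese had log2 fold changes of 1.17 and 0.93 in the authors' deposited table, and the zinc finger gene Z166 and the regulator Six3 -1.34 and -0.58. The Six3 gene is also counted in the apical neural list. Mitf (-1.18) and Pax6 (-1.502), named after their values were seen, were negative in the authors' deposited table as well. Both Scl copies (1.60 and 1.62) and Gcm (0.76), likewise named after their values were seen, were positive there. The pigment cell genes Pks1 and Fmo2 (LOC589643) had -1.60 and -1.92 in the authors' deposited table. Both Delta copies, which encode the Notch ligand, were positive (adjusted p = 0.53), at 1.02 and 1.46 in the authors' deposited table. Of the Wnt ligands, Wnt4 had 1.01 and Wnt6 -0.92 in the authors' deposited table (adjusted p = 1). All 4 genes matched by name to the Wnt pathway components were negative (adjusted p = 0.38), including Sfrp1/5 (LOC100891516) at -1.38 and Dkk3 at -1.17 in the authors' deposited table. The Wnt inhibitor gene Wif (-2.55 there) belongs to this list but was missed by the name match. The oral ectoderm list split into 2 positive and 2 negative genes (adjusted p = 1). The regulators FoxG and Gsc had -1.96 and -1.68 in the authors' deposited table. The TGF-beta receptor gene Alk4-5-7 and FoxJ1, which also stands in the cilia list, had 1.14 and 0.75 there.

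Genes of cell stress and p53 were positive for 3 and negative for 2 (adjusted p = 1), with Gadd45 at 1.42 in the authors' deposited table. The early blastula list had 2 positive and 3 negative genes and the cilia list 3 of each (adjusted p = 1 for both). Morphogenesis and adhesion genes were positive for 2 and negative for 6 (adjusted p = 0.58), with the laminin gene Lama1 (LOC579603) at 1.06 and RhoA at -1.04 in the authors' deposited table. In the remaining lists, FGF (Fgf9/16/20) had -1.82, Vegf3 0.54 and Tbx2/3 -0.85 in the authors' deposited table, which gives 1 positive and 1 negative gene for FGF, VEGF and MAPK signalling and 1 negative gene for the other T-box factors (adjusted p = 1 for both). The brachyury list holds 1 gene (adjusted p = 0.87).

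The largest fold changes among genes with a usable name included copies of repeated names. Positive extremes in the authors' deposited table included a sarcosine oxidase-like gene (LOC115919376) at 7.97, a zinc finger gene (LOC115923083) at 7.11 and a beta tubulin copy (LOC115924527) at 6.36. Negative extremes in the authors' deposited table included a cytochrome P450 copy (LOC105438553) at -9.52, a nucleolin-like gene (LOC105445258) at -9.42 and another beta tubulin copy (LOC594413) at -7.56. Near-identical copies of this kind are uncertain.

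ChIP-seq gave a shorter peak list for antibody library 1 than for antibody library 2. Scores, folds and false discovery rates are the authors', and whether they are on 1 scale in both lists is unknown. Antibody library 1 had 1484 peaks of 136 bp with a median score of 0.57, a maximum of 5.33 and a median fold of 3.52 over input. Antibody library 2 had 7459 peaks of 284 bp with a median score of 0.72, a maximum of 41.68 and a median fold of 2.36. No peak of library 1 had a false discovery rate under 10%, its lowest being 10.87%. In library 2, 1628 peaks were under 10%. The rate did not fall with the score: the peak of score 29.24 in library 2 carried 83.33%. The combined set holds 490 peaks, of which 488 are peaks of library 2 and 2 are peaks of library 1, and 170 of the 490 overlap a peak of library 1. With 1 list per antibody library there is no replicate check of a peak.

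The lists shared more regions than random placement gave. By at least 1 bp, 249 peaks of library 1 (16.8%) overlapped a peak of library 2, and 249 peaks of library 2 (3.34%) overlapped library 1. With midpoints within 50 bp the shares were 9.23% and 1.84%, from 137 peaks of each. Among 1000 random placements of the library 2 peaks on the same scaffolds, the median overlap was 6 peaks and the highest 16 (permutation test, one-sided p = 0.001, the smallest these placements can give). Shared peaks had higher scores. The median score was 1.13 in shared against 0.71 in unshared peaks of library 2, and 0.60 against 0.56 in library 1 (two-sided permutation tests, p = 1e-05 each, the smallest they can give).

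Combined peaks lay inside gene spans about as often as randomly placed ones. Of 489 combined peaks on the paired scaffolds, 248 (50.7%) had their midpoint in a protein-coding gene span, against 49.7% in random placements (two-sided permutation p = 0.62). Within 1 kb of a gene the share was 55.8% against 54.8% (permutation p = 0.69). The full lists differed: 65.3% of library 1 peaks and 68.3% of library 2 peaks lay inside genes, against 49.8% and 50.8% in random placements (permutation p = 0.002 each, the smallest a two-sided test can give here). The gene table gives no strand or exons, so promoters, exons and introns are not analysed here, and the scaffold of each gene was inferred from the order of the table.

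Peaks clustered at the brachyury gene itself. Its span covers NW_022145607.1 from 32932889 to 32949306 in Spur_5.0, and 7 combined peaks lie inside it, with 9 within 20 kb. The highest, at 32948307 to 32948590, had a score of 9.91 and a fold of 16.26 over input, and the next, at 32934172 to 32934455, had a score of 9.51. The authors' false discovery rates of these peaks were 47.14% and 45.83%. Over the 7 peaks inside the gene the rate ran from 9.97% to 47.14%.

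**Figure D2:**
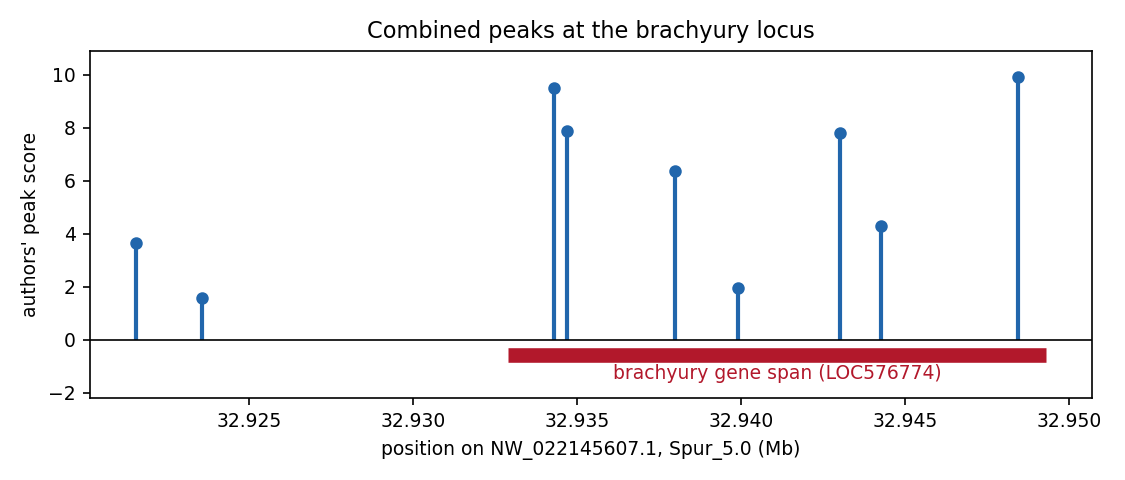
Combined peaks at the brachyury locus: x axis, position on NW_022145607.1 in Mb; y axis, the authors' peak score; the red bar is the gene span. The 7 peaks inside the span reach a score of 9.91.

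Of the 10 highest combined peaks, all from library 2, 4 lay in or near a gene with a name and 6 at genes without a name in the files used here, and no test asked whether high peaks favour regulators. A peak of score 33.85 lay inside Nanos2, a germline regulator, and peaks of 26.41 and 20.84 lay inside GATAe, an endoderm regulator; neither gene is in the differential table. The peak of score 23.66 lay 8355 bp from a Dac copy (LOC115918252), whose log2 fold change was 0.64 in the authors' deposited table. The 2 highest scores, 41.68 and 37.31, lay inside LOC581646, which is among those without a name. The authors' false discovery rates of these 2 peaks were 0% and 33.33%. The rate was 57.14% for the Nanos2 peak, 82.35% and 78.57% for the GATAe peaks and 82.5% for the Dac peak. The receptor gene FGFR held 15 combined peaks, the most of any gene, followed by brachyury with 8 within 10 kb and by Tbx2/3 and GATAe with 4 each.

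Genes with a combined peak lay on both sides of the table. With each peak given to the nearest protein-coding gene within 10 kb, 363 peaks marked 294 genes, and 73 of these are in the differential table. On the negative side, the authors' deposited table lists 12 bound genes matched by name to the fixed lists: Isl (-3.15), hedgehog (-2.31), FGF (-1.82), Msx (-1.69), Pks1 (-1.60), SPEC1 (-1.35), Tbx2/3 (-0.85), Tgif (-0.68), FoxA (-0.67), Six3 (-0.58), Macf1 (-0.45) and a laminin beta gene (LOC582206, -0.36). On the positive side, the 6 bound genes matched by name to the fixed lists in the authors' deposited table were brachyury (1.18), Lama1 (1.06), Delta (1.02), Gcm (0.76), Dac (LOC115918252, 0.64) and Otx (0.56). The Wnt inhibitor gene Wif, named after its value was seen, was bound and had -2.55 in the authors' deposited table. The fixed list of Wnt pathway components holds Wif1, but the name match missed this gene, so the list counts leave it out. Other genes could be missed in the same way. Bound here means only that a combined peak was assigned, whatever its score or false discovery rate. The peak score was 0.78 for Pks1 and 0.66 for the laminin beta gene, against 9.91 for the highest brachyury peak.

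Binding did not separate the directions in the combined set. A combined peak marked 36 of 1482 positive genes (2.43%) and 37 of 1496 negative genes (2.47%), an odds ratio of 0.98 (two-sided Fisher's exact test, p = 1). Among genes with an absolute log2 fold change of at least 1 the odds ratio was 0.58 (Fisher's exact p = 0.23). The full lists gave another result, with peaks more frequent at positive genes. Both lists reach down to a score of 0.5, close to their medians of 0.57 for library 1 and 0.72 for library 2. The comparison was not repeated with their higher-scoring peaks alone. Library 1 marked 7.35% of positive and 3.81% of negative genes (odds ratio 2.00, Fisher's exact p = 2.9e-05), and library 2 marked 29.8% and 17.05% (odds ratio 2.06, p = 2e-16).

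**Figure D3:**
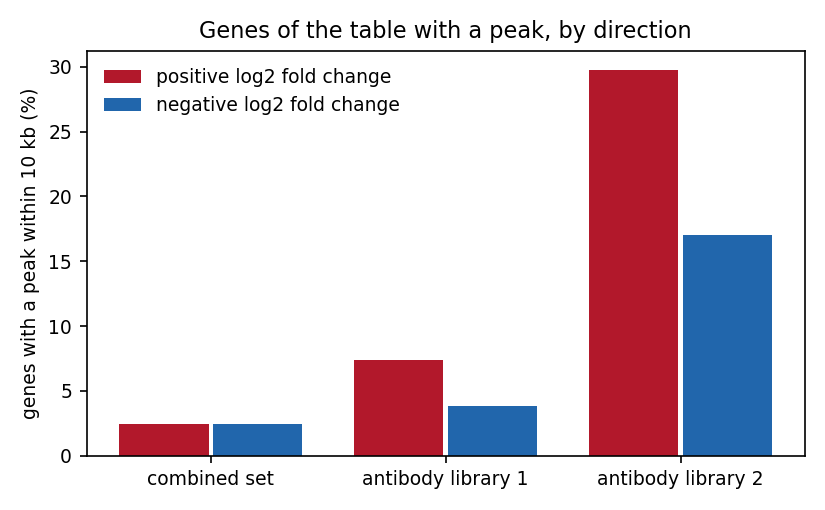
Share of positive (red) and negative (blue) table genes with a peak within 10 kb (y axis, %), for the combined set and each antibody library. The combined set gives 2.43% and 2.47%, library 2 gives 29.8% and 17.05%.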

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

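The tests of gene length in this part were chosen after the overlaps had been seen, as was the comparison with shifted scaffold pairings. Antibody library 1 had 78 peaks on the mitochondrial genome and library 2 had none. They count among the unshared peaks of library 1 in the comparisons of overlap and score, and lie outside the comparisons with genes. Without them 17.7% of library 1 peaks were shared, and the median scores of shared and unshared peaks were 0.60 and 0.55 (permutation p = 1e-05). The median fold over input of the mitochondrial peaks was 1.39, against 3.59 for nuclear peaks of the same list (two-sided permutation test, p = 1e-05, the smallest it can give).

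Genes with a combined peak were more frequent in the differential table than genes without one (Fisher's exact test, odds ratio 2.45, p = 1.1e-09). Of the 294 genes with a peak, 73 were in the table (24.8%). The share among all 24773 protein-coding genes, bound ones included, was 12.0%. Bound genes are longer, with a median span of 20792 bp against 10125 bp, but within length groups the odds ratio stayed at 1.91 (permutation p = 0.0001, the smallest 10000 draws can give), which argues against length as the whole cause. Peaks moved onto the genes of other scaffolds in 20 shifted pairings marked 32 to 48 table genes, with odds ratios of 0.99 to 1.66, above 1 in 19 of them, so 2.45 is to be read against that range rather than against 1; within length groups they gave 0.77 to 1.32 against 1.91, which argues against placement near genes alone. It remains open whether genes active at this stage are both more often bound and more often measurable, since the measured genes outside the table are not analysed here and the 24.8% cannot be set against them. A direct effect of Brachyury therefore stays a hypothesis.

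Peaks of library 2 lay more often at positive than at negative table genes (odds ratio 2.06), while the combined set gave 0.98. Positive genes had longer spans, with medians of 17826 and 13235.5 bp (permutation p = 0.0001), and length could have produced the difference. Within length groups the odds ratio was 1.83 (permutation p = 0.0002) for library 2 and 1.73 (p = 0.0018) for library 1, against 0.82 (p = 0.48) for the combined set, which for the 2 libraries argues against length as the whole cause. Signal from open or transcribed chromatin was not tested.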

How the results depend on the processing

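The alternatives with 1 gene per list member, with the removed rows kept, without Nk7 and Clect_2, with all annotated genes and without mitochondrial peaks were chosen after seeing the data. No paired analysis was possible because the table gives no values per library, although control and morphant libraries share replicate numbers; for the same reason leaving out replicates, other splits of the samples, other scalings and filters on level were not run. A reciprocal overlap of 50% cannot occur between peaks of 136 and 284 bp and gave no value. With 1 gene per list member the lists past the threshold went from 3 to 2, as skeletogenic genes lost the call (adjusted p = 0.48). Leaving out Nk7 and Clect_2 kept all 3. The table kept 2209 genes at an adjusted p under 0.01 and 1910 at an absolute log2 fold change of at least 1, with the share of positive genes going from 48.4% to 44.6% and 39.6%. The higher-scoring part of each list holds 742 and 3729 peaks by construction, and a fold of at least 5 left 280 and 399 for libraries 1 and 2. The share of library 1 peaks with a partner in library 2 fell from 16.8% to 9.23% for midpoints within 50 bp and was 17.9% among the higher-scoring peaks and 17.7% without mitochondrial peaks (permutation p = 0.001 each). The share of combined peaks near genes was 64.4% within 5 kb against a random 67.9% (permutation p = 0.11). Within 1 kb it was 68.6% for the list of library 1 and 70.9% for that of library 2, against random shares of 55.1% and 56.1% (permutation p = 0.002 each). The odds ratio of binding at positive against negative genes crossed 1 without passing the threshold within 5 kb (1.01), within 50 kb (1.13) and at an adjusted p under 0.01 (1.00), and passed it for the lists of libraries 1 (2.00) and 2 (2.06). It fell to 0.58 (Fisher's exact p = 0.23) at an absolute log2 fold change of at least 1 and was 0.90 with all annotated genes, on the same side of 1. Of the possible causes only gene length was tested, for the combined set and both libraries. Depth is unknown for all libraries.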

Other observations

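All tests of this part were chosen after the table had been seen. They treat genes as independent, as the list tests do, so their p-values do not measure replication over embryos. Ribosomal protein genes by name were negative for 67 of 68 genes, with a median log2 fold change of -1.21 in the authors' deposited table (exact binomial p = 2.9e-18 against the 48.4% positive among all table genes). The exception is a partial model of Rpl7a (LOC574574) at 6.13 in the authors' deposited table. The 68 genes include those of the housekeeping list, and the translation class below may hold the same genes. These results are therefore not separate evidence. By the first functional class of each gene in the table, translation genes were negative for 93 of 104 and nervous genes for 40 of 57 (Fisher's exact test over 8 classes, adjusted p = 7.1e-16 and 0.0064). The 8 classes were picked by hand, and the adjustment covers only these 8. Zinc finger genes were positive for 55 of 67 and cell cycle genes for 27 of 34 (adjusted p = 6.4e-08 and 0.00061). Metabolism genes were negative for 176 of 261 and biomineralization genes for 24 of 26 (adjusted p = 2.8e-07 and 2.5e-05). With 1 gene per name stem, the one with the smallest adjusted p, biomineralization genes were negative for 14 of 14 (adjusted p = 8.6e-05), a choice that dropped the 2 positive genes, and the same 6 classes passed the threshold. Transcription factors, as a first class, were positive for 21 and negative for 20 (adjusted p = 0.86), and signaling genes for 16 and 18 (adjusted p = 1).

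A wider set, the 81 table genes on paired scaffolds with transcription factor in a GO term or in any functional class, was common among bound genes: 11 of 73 bound table genes (15.1%) against 70 of 2905 unbound ones (2.41%). Random table genes of the same lengths gave a median of 2 (length-matched permutation p = 0.0001, the smallest 10000 draws can give), and the shifted pairings at most 4. A hypothesis is that the peaks lie preferentially at regulatory genes of the table. The space between genes, which can be wide around regulators, was not tested.

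The largest changes may reflect reads assigned to 1 of several near-identical copies. Of the 125 genes with an absolute log2 fold change over 5, 34.4% share their transcript model ID with another gene of the table, against 21.5% of the others (Fisher's exact test, p = 0.0013). Of 32 such model IDs with an extreme gene, 17 had copies of both signs, against 37 of all 337 model IDs on several genes. Only 16.8% of the extreme genes had a usable name, against 56.2% of the others (Fisher's exact p = 6.7e-19). Differences between the parents of the embryos were not tested.

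A hypothesis that negative values mean lower in morphants could not be decided from the effector list, where 3 of 4 distinct members were negative (exact binomial p = 0.63); with 4 members this test could not pass 0.05 whatever their signs. Another, that morphants and controls differ in developmental progress, was tested on mesoderm members, sorted by hand into products and regulators after their values were seen. Products were negative for 12 of 14 and regulators for 6 of 12 (Fisher's exact test, p = 0.09). The early blastula list, expected to lean to the positive side, had 2 positive and 3 negative genes. Its 5 genes could have reached an unadjusted exact binomial p of 0.027. Neither part of the prediction was met, but with so few members the hypothesis was not excluded. The labels name no embryos injected with an unrelated morpholino, so effects of injection and of brachyury loss were not separated.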
